A study of Mus musculus with 12 samples.

How the data were processed

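RNA from bone marrow-derived macrophages of wild-type and Nod2-deficient mice, uninfected or infected with Neisseria gonorrhoeae strain MS11, was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, 3 wells for each of 4 groups. The authors deposited 1 log2 expression value per probe set and array, normalized by RMA at probe level per the submitters' design text; the version and settings of RMA are not stated. RMA corrects background, makes the arrays' distributions comparable and summarises probes on the log2 scale, and it compresses differences near background. The table holds 35557 probe sets. The platform annotation pairs 23410 of them with at least 1 gene symbol, and these were tested; 21789 have exactly 1 symbol, 1621 several and 12147 none. Symbols were checked through the Entrez identifier for 21698 probe sets. For named genes, gene lists and correlations, a gene was represented by its 1-symbol probe set with the highest mean over all arrays, which gave 19938 genes, 999 of them with over 1 probe set. Ripk2 and the other listed genes without such a probe set were not analysed here. Among named genes with several probe sets, those of Fdft1, Socs3, Cd80 and Top2a differed. The second probe set of Fdft1 changed by 0.20 in place of -0.05 on infection in wild-type cells, with an interaction of -0.12 in place of 0.12. That of Socs3 rose by 3.18 in place of 6.26 in wild-type cells and 3.85 in place of 6.21 in cells labelled knockout, with an interaction of 0.67 in place of -0.05 and genotype differences of -0.28 in place of 0.06 in uninfected and 0.39 in place of 0.01 in infected cells. That of Cd80 differed by -0.07 in place of 0.25 between uninfected genotypes, and that of Top2a, with a mean of 1.59, by -0.11 in place of -1.66.

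The series design names a 2-way model of genotype, infection and their interaction. All 12 arrays were fitted by limma 3.58.1 in R 4.3.3 as means of the 4 groups with moderated variances, which gives the same means and shares 1 estimate of the spread. Contrasts were infection in each genotype, genotype in each infection state, their difference (the interaction) and the 2 averages. Tests were two-sided with Benjamini-Hochberg adjustment over 23410 probe sets, and a probe set was called at an adjusted p under 0.05; adjusted p-values in the text are from these fits. On simulated arrays with 200 changed probe sets among 23410, a log2 change of 1 was recovered for 98% in the infection contrasts, 92% for the interaction, 100% for genotype in uninfected and 96% for genotype in infected cells, and a change of 0.5 for 66%, 70%, 25%, 73% and 66% of the infection contrast in wild type, that in knockout, the interaction and the genotype contrasts in uninfected and infected cells. In that order, 12 of 177, 12 of 181, 8 of 129, 8 of 181 and 5 of 169 calls were false. The simulated noise was independent between probe sets. Far fewer probe sets changed than the 39.3% and 41.5% called on infection in the 2 genotypes. Fewer also changed than the 7.49% and 5.84% called between genotypes in uninfected and infected cells. The simulated shares need therefore not hold for the infection or the genotype contrasts.

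Before the data were examined, 23 gene lists were fixed, 14 of pathways or functions and 9 of cell types other than macrophages that the cultures could hold. The pathway lists covered immediate early transcription factors, the NF-kB pathway, cytokines, chemokines, interferon response, pattern recognition and NOD signalling, inflammasome and pyroptosis, antimicrobial and oxidative effectors, antigen presentation, autophagy, cell cycle, sterol synthesis and efflux, glycolysis and hypoxia, and macrophage identity. The marker lists covered monocytes, neutrophils and their precursors, dendritic cells, T and NK cells, B cells, mast cells and basophils, fibroblasts and stroma, osteoclasts and erythroid cells. Lists were tested in 5 contrasts with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists of a contrast, and again with the correlation estimated for each list. Counts of called members use the adjustment over all probe sets, and a count adjusted over the list alone is given beside many of them. Nr4a1, Lcn2, Il1b and Il18 are each in 2 lists.

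Named genes followed a rule fixed in advance: the 12 largest rises and 8 largest falls of each infection contrast and the 10 largest in each direction of the other contrasts, among called genes whose 3 arrays of 1 group all lay above the 3 of the other, up to 4 called members of each list by size, and 12 genes of the NOD and cytokine response, 11 of which were measured. For the interaction, the arrays compared were each infected array minus the mean of its genotype's uninfected arrays. Genes known only by a provisional symbol were passed over, which left out 1 in the interaction. Genes next to Nod2 were taken in the order of the GRCm38.p6 annotation, used for order only because the build of the array annotation is not given, and compared with other genes by Fisher's exact test.

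Alternatives were the 2-way linear model without variance moderation, a variance trend with robust prior, removal of dim probe sets, all probe sets, 1 probe set per gene, renewed quantile normalization, median centring, only the groups compared, the replicate number as a block, array weights, a 2-fold threshold and leaving out each array. Leaving out both arrays that stood apart was added after seeing the data. Figures were drawn with matplotlib 3.10.9.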

Results

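Gene expression was measured in bone marrow-derived macrophages, phagocytes grown from mouse bone marrow in culture, on 12 whole-transcript arrays. The cells came from wild-type C57BL/6 mice or from mice lacking Nod2, a cytosolic sensor of bacterial peptidoglycan fragments. They were left uninfected or exposed for 3 hours to Neisseria gonorrhoeae, the Gram-negative agent of gonorrhoea, at 10 bacteria per cell. The 4 groups held 3 arrays each, 1 per culture well, and the experiment was done once. Every p-value of a single gene below therefore measures only the spread between wells of 1 experiment. List tests and Fisher's exact tests compare genes with other genes, which are not independent replicates. Their p-values measure neither the spread between wells nor that between experiments. Array medians of the deposited log2 values lay between 4.59 and 4.67, and no detection call is given, so values near the low end are compressed and the number of arrays limits the precision. Arrays of a group correlated at 0.991 to 0.995 across all probe sets, against 0.963 to 0.969 across infection states. The first principal component held 83.4% of the variance and the second 6.68%. The third infected array labelled Nod2 knockout stood apart in fibroblast and stromal markers, with a list mean of 6.59 against 5.58 and 5.66 on the other arrays of its group. The third uninfected array labelled Nod2 knockout had the widest scatter, with 52 probe sets over 0.5 log2 units from the group mean.

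The first question was whether the Nod2 transcript itself separated the genotypes. It did not: uninfected wild-type arrays read 4.62 ± 0.04 and those labelled Nod2 knockout 4.62 ± 0.18 (log2, mean ± SD, n = 3), a difference of -0.003 ± 0.103 (SE, adjusted p = 0.994). In infected cells the means were 7.15 ± 0.20 and 6.96 ± 0.01, a difference of -0.19 ± 0.103 (adjusted p = 0.391). Nod2 rose 5.78-fold on infection in wild-type cells and 5.08-fold in those labelled knockout. The description of the mice does not give the allele or the deleted part, and the files do not place the probes within the gene, so this probe set may lie outside the deletion and then checks nothing. Every genotype direction below rests on the labels.

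The infection contrast in wild-type cells asked what the bacteria changed within 3 hours. Among inflammatory cytokines Il1a rose 542-fold (log2 change 9.08 ± 0.145 SE), Il6 374-fold, Il12b 285-fold and Il1b 275-fold, n = 3 arrays per group. Their uninfected means were as low as 3.04 for Il1a and 2.59 for Il6, near the low end, so the order of the largest folds is not secure. The neutrophil-attracting chemokines Cxcl2 and Cxcl3 rose 304-fold and 156-fold, and Acod1, which makes itaconate, rose 226-fold. Ptgs2, the inducible cyclooxygenase, rose 192-fold, the activation marker Cd69 205-fold, the interferon-inducible genes Gbp5 and Ifi205 196-fold and 186-fold, and the endothelin gene Edn1 124-fold. Tnf rose 95.6-fold, Cxcl10 101-fold, the anti-inflammatory Il10 50.6-fold, the inducible nitric oxide synthase Nos2 31.0-fold and Ifnb1 6.48-fold. The uninfected means of Ifnb1 (2.9), Nos2 (4.14) and Il10 (4.23) lay below the array medians. So did those of Il1a, Il6, Il12b, Il1b, Cxcl2, Cxcl3, Cd69, Gbp5, Ifi205 and Edn1, and the sizes of all these folds are not secure. The largest falls were in Sesn1, a stress-responsive regulator of mTORC1, at 35.8-fold, followed by Lpar6 at 27.6-fold, Arrdc3 at 27.4-fold, the chemokine receptor Cxcr4 at 26.0-fold, Cd300lb at 20.7-fold, Abcd2 at 15.9-fold, Lhfpl2 at 14.2-fold and Trp53inp1 with a log2 change of -3.81.

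Of the fixed gene lists, 20 of 20 measured NF-kB pathway genes rose in wild-type cells (median log2 change 3.13, adjusted p = 9.64e-27), led by Socs3 at 76.4-fold and Tnfaip3 at 74.1-fold. Cytokines rose in 23 of 24 members with 1 falling (median 4.20), chemokines in 19 of 20 (median 5.46) and interferon response genes in 25 of 25 (median 4.36), the last led after Gbp5 and Ifi205 by Mx2 at 94.1-fold. Gbp5, Ifi205 and Mx2 all read below the array medians in uninfected wild-type cells, so this fold and the order are not secure. Antimicrobial and oxidative effectors rose in 14 of 18 with 1 falling (median 2.82), including Slc7a11 at 67.2-fold and Saa3 at 67.0-fold. Slc7a11 read 3.58, 3.89 and 4.3 on the uninfected wild-type arrays, below their medians, so its fold is not secure. Immediate early transcription factors rose in 12 of 16 with 3 falling (adjusted p = 9.59e-05), among them Ier3 at 15.2-fold and Maff at 11.2-fold. The uninfected mean of Maff, 4.48, also lay below the array medians, so its fold is not secure either. Antigen presentation and co-stimulation genes rose in 11 of 17 (adjusted p = 5.64e-07), with Cd40 at 33.0-fold and Cd274 at 23.5-fold, and pattern recognition genes rose in 12 of 22 with 5 falling (adjusted p = 0.000276), with Tlr2 at a log2 change of 3.17. Cell cycle genes fell in 24 of 25 members (median -0.78, adjusted p = 6.70e-12), with Ccne2 at a log2 change of -2.20, and autophagy genes fell in 15 of 21 with 2 rising (median -0.60, adjusted p = 9.59e-05), with Nbr1 down 3.05-fold. Macrophage identity genes fell in 10 of 21 with 1 rising, including Cebpa by 6.85-fold and Mertk by 4.69-fold, at adjusted p = 0.0135 (adjusted p = 0.0842 with an estimated correlation); the other 10 list calls held with an estimated correlation. Adjusted over the list alone, the counts of these 11 lists were the same except for 13 pattern recognition genes rising.

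The remaining lists were not called in wild-type cells. Within the inflammasome list (adjusted p = 0.0889), Nlrp3 rose 17.5-fold and Casp4 9.28-fold while Nlrp1b fell 3.49-fold. Within the glycolysis and hypoxia list (adjusted p = 0.454), Pfkfb3 rose 11.5-fold and Slc2a1 3.63-fold; its median was -0.09, its mean 0.36 and the direction of its test up. Sterol genes went both ways (adjusted p = 0.487), with the efflux pump Abcg1 down 3.19-fold and Idi1 up 1.71-fold. Adjusted p was 0.876 for monocyte, 0.0548 for neutrophil, 0.119 for dendritic cell, 0.359 for T and NK cell, 0.845 for B cell, 0.112 for mast cell, 0.375 for fibroblast, 0.530 for osteoclast and 0.518 for erythroid markers. The monocyte list had a median of -0.02 and a mean of -0.08 with its test direction up, and the B cell list a median of 0.08 and a mean of -0.03 with its test direction up. In all, 9193 of 23410 probe sets were called (limma with Benjamini-Hochberg adjustment), 3413 higher and 5780 lower, and 1912 of them changed at least 2-fold.

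The same contrast in cells labelled Nod2 knockout asked whether the response took place there too. Il1a rose 690-fold (log2 change 9.43 ± 0.145 SE), Il12b 350-fold, Il6 334-fold, Cxcl2 325-fold and Il1b 279-fold, n = 3 arrays per group. Tnfsf9, a ligand of the tumour necrosis factor family, rose 165-fold, Edn1 159-fold, Gbp5 147-fold, Acod1 146-fold, Cxcl3 140-fold, Ptgs2 134-fold (log2 change 7.06) and the chemokine Ccl7 132-fold. Tnf rose 76.3-fold, Cxcl10 65.8-fold, Il10 56.4-fold, Nos2 17.4-fold and Ifnb1 8.59-fold. Sesn1 fell most, at 39.6-fold, then Arrdc3 at 32.8-fold, Lpar6 at 28.7-fold, Abcd2 at 18.6-fold, Cd300lb at 18.2-fold, Cxcr4 at 17.6-fold, Fam214a at 15.6-fold and Klhl6 at 15.4-fold. These were 9726 called probe sets of 23410, 3617 higher and 6109 lower, with 1964 changed at least 2-fold. The share higher was 37.2%, against 44.5% after renewed quantile normalization and 34.1% after median centring. Uninfected means of 2.83 for Il1a and 2.69 for Il6 again leave the order of the largest folds insecure. Those of Il12b, Cxcl2, Il1b, Tnfsf9, Edn1, Gbp5, Cxcl3, Il10, Nos2 and Ifnb1 also lay below the array medians. The sizes of all these folds are not secure either.

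In cells labelled knockout the NF-kB list again rose in 20 of 20 members (median 2.95), cytokines in 23 of 24 with 1 falling (median 3.83), chemokines in 19 of 20 (median 4.99), interferon response genes in 24 of 25 (median 3.21) and antimicrobial effectors in 13 of 18 with 1 falling, or 2 adjusted over the list alone (median 2.53). Immediate early factors rose in 12 of 16 with 2 falling (adjusted p = 2.23e-05), antigen presentation genes in 9 of 17 (11 adjusted over the list alone; adjusted p = 1.37e-05) and pattern recognition genes in 13 of 22 with 5 falling, or 6 adjusted over the list alone (adjusted p = 0.00177). Adjusted over the list alone these counts of rising genes were otherwise the same. Cell cycle genes fell in 23 of 25 with 1 rising (median -0.65, adjusted p = 2.04e-08) and autophagy genes in 14 of 21 with 2 rising (median -0.74, adjusted p = 4.03e-05). Macrophage identity genes fell in 11 of 21, or 14 adjusted over the list alone, at adjusted p = 0.00754 (adjusted p = 0.0594 with an estimated correlation). Neutrophil markers rose in 8 of 15 (median 0.31, adjusted p = 0.00909), with Lcn2 up 6.90-fold and S100a9 up 1.87-fold. Fibroblast markers were called higher with 3 of 12 members (0 adjusted over the list alone) at adjusted p = 0.0402 (adjusted p = 0.530 with an estimated correlation), and no member was called without the third infected array labelled knockout. The other 10 lists were not called; among them the glycolysis list had a median of -0.11 and a mean of 0.38, the monocyte list a median of 0.19 and a mean of -0.14, the B cell list a median of 0.05 and a mean of -0.01, and the erythroid list a median of 0.02 and a mean of -0.009, all 4 with the test direction up.

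Gene by gene, the infection responses of the 2 genotypes ran close together. Across 19938 genes, which are not independent replicates, the log2 changes correlated at r = 0.966 (Spearman 0.848), with a slope of 0.953 for the change in cells labelled knockout on that in wild type. Of 6818 genes called in both, 6810 moved the same way. The 8 that moved oppositely were chosen after their values were seen. E2f8 (-1.18 in wild type and 0.22 in cells labelled knockout, interaction adjusted p = 4.02e-05) and Tbc1d9 (-0.49 and 0.31, 0.00226) also had a called interaction. So did Irf8 (0.0458), Mgat3 (0.0467) and Niban3 (0.0385), closer to the threshold, whereas H60b, Vmn1r67 and Zmynd19 did not; Tbc1d9 and these last 6 were not refitted with arrays left out.

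**Figure D1:**
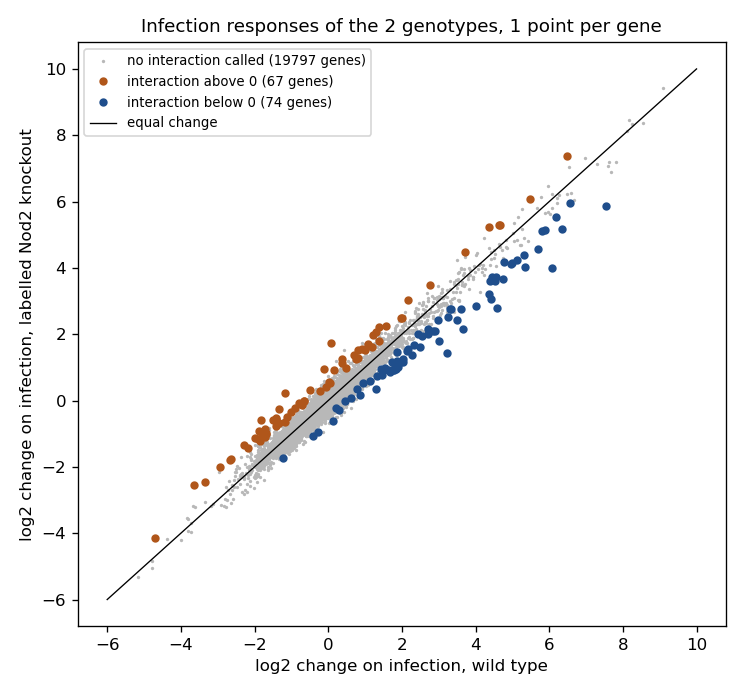
Each point is 1 of 19938 genes, placed by its log2 change on infection in wild-type cells (horizontal axis) and in cells labelled Nod2 knockout (vertical axis). The points follow the line of equal change (r = 0.966), with 67 genes coloured for a called interaction above 0 and 74 for a called interaction below 0.

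The interaction asked which genes responded to infection differently in the 2 genotypes. Among genes that rose less in cells labelled Nod2 knockout were the serum amyloid gene Saa3, by -2.07 ± 0.229 (log2 difference of the changes, SE), the siderophore-binding Lcn2 by -1.80 ± 0.108, Ms4a4c by -1.79, Ifi205 by -1.66, Ifi206 by -1.37 and Ifit3 by -1.15, n = 3 arrays per group. The chemokines Ccl17 (-1.51) and Ccl5 (-1.18), the collagenase Mmp13 (-1.31), complement factor Cfb (-1.20) and the growth factor Csf1 (-0.91) were also lower. Ccl17 lies within 200 measured genes of Nod2, a part of the chromosome weighed below. Above 0 stood the zinc-finger gene Zfp961 (1.67 ± 0.118), the cell cycle repressor E2f8 (1.41) and the division genes Aspm (1.21), Depdc1b (1.09), Mki67 (1.06), Nsl1 (0.97), Cdca2 (0.94) and Ccne1 (0.91). The distance of Zfp961 from Nod2 is not given here, so DNA from another strain is not excluded for its difference. After infection Aspm read 4.40 and 3.90 in wild-type cells and cells labelled knockout, Depdc1b 4.43 and 4.29, Nsl1 4.80 and 4.69 and Cdca2 5.34 and 4.65. At least 1 mean of each lay near or below the array medians, where values are compressed, so the size of these 4 differences is not secure. Among cytokines, Tnfsf9 (0.89), Il23a (0.87) and Lif (0.87) rose more in cells labelled knockout. The same limit holds from the uninfected side for Tnfsf9, Lif, Il23a, Lcn2, Ifi205 and Ccl17, with wild-type means of 4.40, 4.44, 4.15, 4.12, 4.27 and 4.68. Tnf (-0.33, adjusted p = 0.640), Il1b (0.02, 0.990), Il6 (-0.16, 0.943), Il10 (0.16, 0.786), Il12b (0.29, 0.732), Ifnb1 (0.41, 0.493), Cxcl10 (-0.62, 0.424), Ptgs2 (-0.53, 0.340), Nod1 (0.07, 0.966) and Nod2 (-0.19, 0.824) had no called interaction. Infected means of Tnf (12.99 and 12.95), Cxcl10 (13.3 and 13.25) and Ptgs2 (12.58 and 12.52) lay near the highest value of any array, 13.67. Their interactions could be compressed there, which was not tested for these genes. Infected means of Ccl5 (12.87 and 12.84) and Mmp13 (12.27 and 12.54), called above, were also high. From their higher start in cells labelled knockout, a ceiling could itself make the rise smaller, which was not tested for them.

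The interferon response list was lower in the interaction, with 17 of 25 members called (23 adjusted over the list alone), a median of -0.60 and adjusted p = 1.21e-40 (adjusted p = 0.00142 with an estimated correlation). With 1 array left out the median lay between -0.63 and -0.56 and 24 of 25 members stayed below 0. The number called fell to 8, 7 and 9 without the first, the second or the third uninfected wild-type array, to 9 and 6 without the first or the second infected wild-type array, to 11 without the second uninfected array labelled knockout and to 8 and 7 without the second or the third infected one. Antimicrobial effectors were lower in 4 of 18 members (7 adjusted over the list alone), namely Saa3, Lcn2, Nos2 (-0.84) and Cybb (-0.54), a subunit of the phagocyte oxidase, with a median of -0.17 and adjusted p = 1.89e-06. The inflammasome list was lower at a median of -0.17 (adjusted p = 0.000556) with 0 of 18 members called (3 adjusted over the list alone). These 3 list calls held with an estimated correlation. The cell cycle list stood above 0 (median 0.13, 2 of 25 members, 4 adjusted over the list alone) at adjusted p = 2.59e-07 (adjusted p = 0.0528 with an estimated correlation). Antigen presentation genes were lower (median -0.18, Cd274 at -0.83 the single called member, 2 adjusted over the list alone) at adjusted p = 0.00574 (adjusted p = 0.330 with an estimated correlation). NF-kB genes were lower (median -0.11, 0 of 20 members called, with 2 higher and 2 lower adjusted over the list alone) at adjusted p = 0.0150 (adjusted p = 0.352 with an estimated correlation). The other 17 lists were not called; the neutrophil list had a median of 0.06 and a mean of -0.01 with its test direction up, the sterol list 0.009 and -0.01 with its direction down, and the glycolysis list -0.02 and 0.02 with its direction up.

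In all, 156 of 23410 probe sets had a called interaction, 73 above and 83 below 0, and 20 of them differed at least 2-fold. The balance of directions turned with the scaling: 46.8% lay above 0, against 51.2% after renewed quantile normalization and 55.7% after median centring. Of 74 genes below 0, 53 differed between the genotypes in uninfected cells only, 10 in infected cells only and 11 in both; 62 were higher in uninfected cells labelled knockout. Of 67 genes above 0, 24 differed in uninfected cells only, 23 in infected cells only and 20 in both. The interaction shares its arrays with both genotype contrasts, so part of this coincidence is built in. Leaving out 1 array lowered the count over 1.5-fold in 10 of 12 fits, to between 60 without the second infected wild-type array and 101 without the first infected array labelled knockout; it was 220 without the third uninfected array labelled knockout. Without that second wild-type array 6 interferon genes were called, and 6 named genes lost their calls, as each did in at least 3 of the other fits with 1 array left out. These were Ccl22 (-1.08 on all arrays; adjusted p = 0.0653 without that array), Ccl24 (0.85; 0.0585), Mx1 (-0.90; 0.0819), Nos2 (-0.84; 0.0626), Fbxo5 (1.10; 0.0932) and Ccnf (0.93; 0.0623). Of these, Ccl22, Ccl24 and Nos2 had low uninfected wild-type means (3.83, 4.62 and 4.14) and Fbxo5 and Ccnf low infected means in cells labelled knockout (4.49 and 4.79), which limits the sizes in the same way. Without both arrays that stood apart, 141 probe sets and 10 interferon genes were called, and Ifi206, Nos2, Ccl22 and Ccnf were not.

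**Figure D2:**
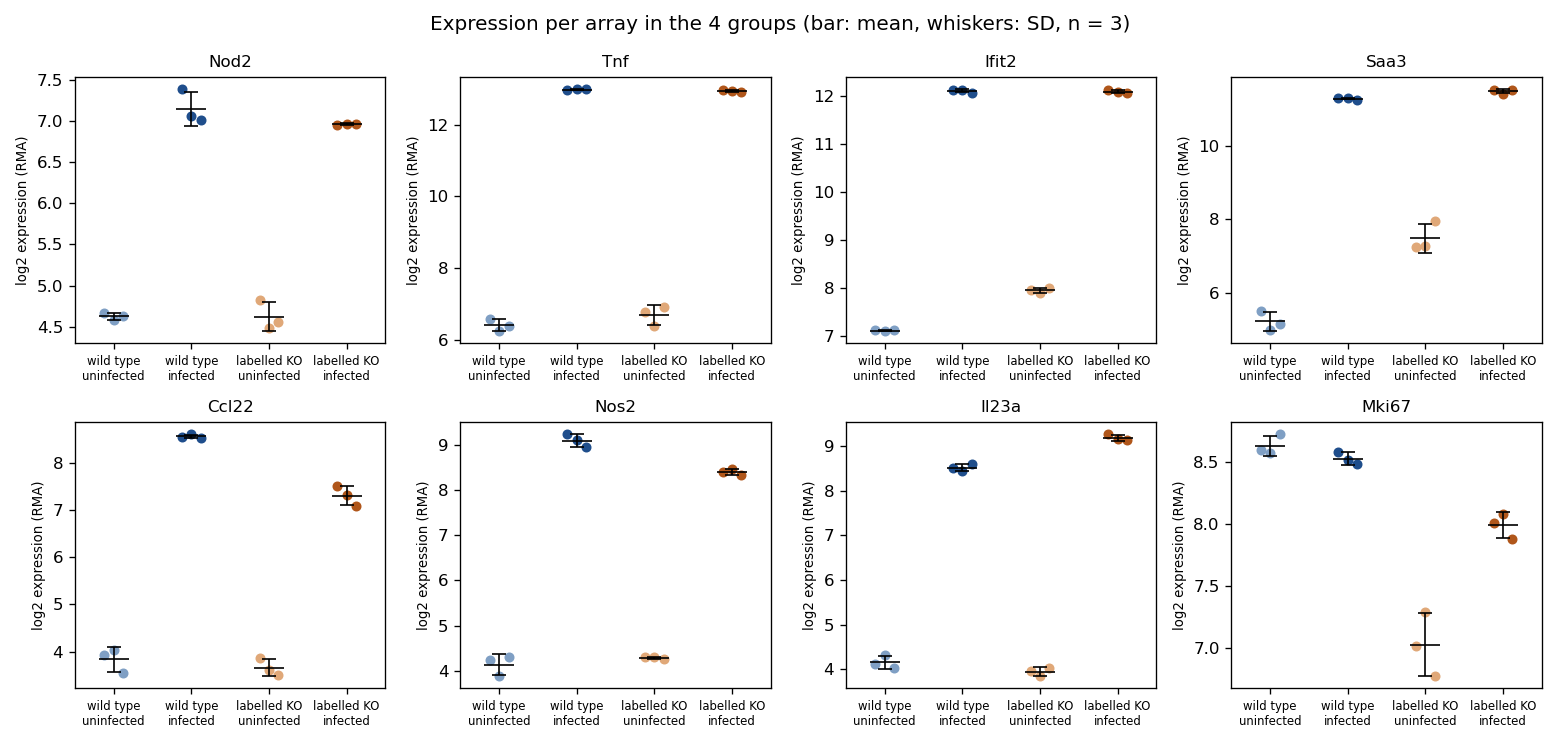
Log2 expression of 8 genes on each of the 12 arrays (points), with group mean (bar) and SD (whiskers), n = 3. Tnf reached 12.99 and 12.95 on infection in the 2 genotypes, Saa3 and Ifit2 started higher in uninfected cells labelled Nod2 knockout, Ccl22 and Nos2 ended lower and Il23a higher there after infection, and Nod2 did not separate the genotypes.

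The genotype contrast in uninfected cells asked what differed before infection. Ms4a4c was 6.33-fold higher in arrays labelled Nod2 knockout (9.25 ± 0.33 against 6.59 ± 0.24, log2, SD, n = 3), Saa3 4.81-fold, Lcn2 4.22-fold, the macrophage elastase Mmp12 4.20-fold, the monocyte attractant Ccl8 3.93-fold, Ifi205 3.64-fold and the granule gene Ngp 3.44-fold. Wdfy1 (3.10-fold, log2 change 1.63 ± 0.086 SE), Chil3 (3.10-fold, log2 change 1.63 ± 0.143 SE) and the chemokine receptor Ccr2 (3.03-fold) completed the 10 largest. The wild-type means of Chil3 (2.60), Ccl8 (4.06), Ngp (4.10), Lcn2 (4.12) and Ifi205 (4.27) lay below the array medians, so these folds and the order of the 10 are not secure. Lower by the largest factors were Hmmr at 4.13-fold, Prc1 3.97-fold, the kinesins Kif20a (log2 change -1.81), Kif11 3.39-fold and Kif2c 3.32-fold, Spag5 3.42-fold, cyclin A2 (Ccna2) 3.36-fold, Aspm 3.27-fold and Esco2 3.26-fold, together with the RNA-binding Igf2bp3 at 3.34-fold. Aspm and Igf2bp3 both read 4.50 in arrays labelled knockout, below the array medians, so their folds are not secure either. The cell cycle list was lower in 23 of 25 members (24 adjusted over the list alone; median -1.20, adjusted p = 4.75e-50). Interferon response genes were higher in 23 of 25 (24 adjusted over the list alone; median 0.59, adjusted p = 1.60e-31), among them Ifit3 at 2.38-fold and Zbp1 at 1.84-fold.

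Antigen presentation genes were higher in 10 of 17 members in uninfected cells labelled knockout (14 adjusted over the list alone; median 0.35, adjusted p = 5.76e-11), with the class II genes H2-Aa 2.93-fold, H2-Ab1 2.41-fold and Cd74 2.26-fold higher. Neutrophil markers were higher in 7 of 15 (7 adjusted over the list alone; median 0.25, adjusted p = 8.82e-09), with Ltf at 2.21-fold and S100a8 at 2.10-fold from low wild-type means of 4.16 and 3.81. Of the 15 measured neutrophil genes 1 lay above the array median on all wild-type uninfected arrays and 1, Lcn2, is also in the effector list. Sterol (median 0.21, adjusted p = 3.89e-06), pattern recognition (median 0.13, adjusted p = 0.00115) and autophagy genes (median 0.11, adjusted p = 0.00197) were higher and glycolysis genes lower (median -0.13, adjusted p = 0.00913), with Nr1h3, a sterol-sensing receptor, 1.47-fold higher, Tlr7 1.37-fold higher and the glucose transporter Slc2a1 1.37-fold lower although 2 other glycolysis genes were called higher. Few members of these 4 lists passed: 5 of 17 sterol, 3 of 22 pattern recognition and 1 of 21 autophagy genes higher and 1 of 17 glycolysis genes lower (10, 7, 4 and 7 adjusted over the list alone). With 1 array left out these counts ranged from 3 to 6, 1 to 3, 1 to 4 and 1 to 4. Those 8 list calls held with an estimated correlation. Lost with it were NF-kB genes (adjusted p = 2.92e-05; adjusted p = 0.0586 with an estimated correlation), antimicrobial effectors (0.00324; 0.0539) and monocyte markers (0.0164; 0.0586). The same held for macrophage identity genes (0.00960; adjusted p = 0.0687 with an estimated correlation), cytokines (0.0306; 0.266) and fibroblast markers (0.000677; 0.322), whose medians were 0.11, 0.11 and 0.46. Within the macrophage list Siglec1 was 2.12-fold higher and Cx3cr1 2.48-fold lower, and within cytokines Csf1 was 1.94-fold higher. Not called were the immediate early (adjusted p = 0.0557), chemokine (0.0957), inflammasome (0.190), dendritic cell (0.604), T and NK cell (0.251), B cell (0.761), mast cell (0.684), osteoclast (0.251) and erythroid (0.616) lists. In all, 1753 of 23410 probe sets were called, 909 higher and 844 lower, and 205 differed at least 2-fold. The share higher was 51.9%, against 48.2% after renewed quantile normalization and 46.5% after median centring.

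**Figure D3:**
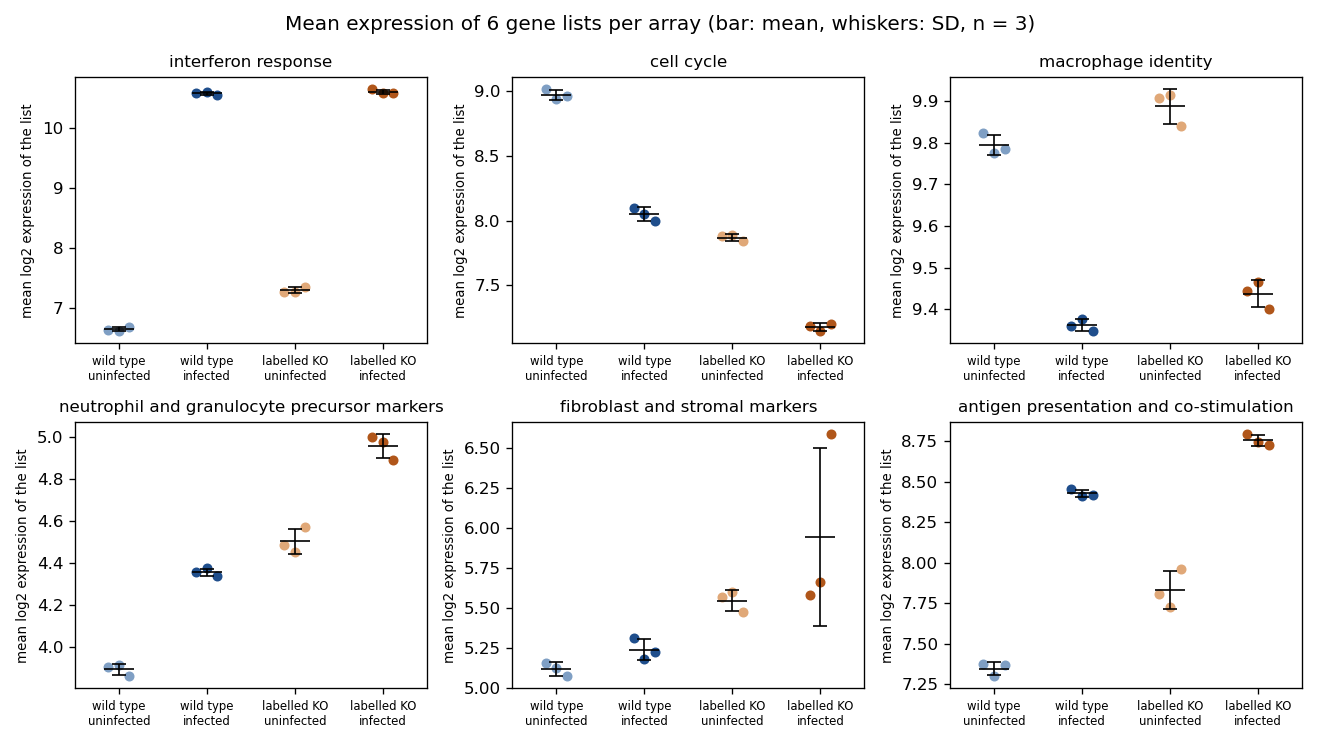
Mean log2 expression of the measured members of 6 gene lists on each array (points), with group mean (bar) and SD (whiskers), n = 3. Interferon response genes averaged 6.64 and 7.29 in uninfected wild-type cells and cells labelled Nod2 knockout and 10.58 and 10.62 after infection, cell cycle genes were lower in arrays labelled knockout in both states, and fibroblast markers reached 6.59 on 1 infected array.

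The genotype contrast in infected cells asked what differed after 3 hours with the bacteria. Ngp was 3.67-fold higher in arrays labelled Nod2 knockout (log2 change 1.87 ± 0.146 SE, n = 3), the antimicrobial calprotectin subunit S100a9 2.63-fold, Ly6a2 3.23-fold, Ccl8 2.94-fold, Fabp7 2.86-fold, Spic, a transcription factor of iron-recycling macrophages, 2.80-fold, H2-Aa 2.79-fold, Ccr2 2.75-fold and Mmp12 2.62-fold. Timp3 was 3.28-fold higher, but it read 8.16 on the third infected array labelled knockout against 6.23 and 6.12 on the others, and its call was lost without the second infected wild-type array (adjusted p = 0.0568). The histones H2ac4 and H1f5 were 3.94-fold and 3.28-fold lower, Anln 3.74-fold, Hmmr 3.71-fold, Prc1 3.64-fold, Kif11 3.63-fold, Bub1 3.49-fold, Ccna2 3.35-fold, Top2a 3.23-fold and Spag5 3.22-fold. Wild-type means of 3.31 for Ly6a2 and 4.82 for Ngp, and means of 4.24 for Hmmr, 4.77 for Spag5 and 4.79 for Anln in arrays labelled knockout, lay near or below the array medians, so these folds and the order are not secure. Ccl17 and Ccl22, ligands of the receptor Ccr4, were 2.47-fold and 2.39-fold lower and Nos2 1.61-fold lower, whereas Ccl24 was 1.80-fold, Lif 1.78-fold and Il23a 1.59-fold higher. Ccl17 and Ccl22 lie within 200 measured genes of Nod2, where DNA from another strain stays open, as weighed below. Tnf (-0.04, adjusted p = 0.920), Il1b (0.10, 0.752), Il6 (-0.06, 0.926), Il12b (0.21, 0.424), Ifnb1 (0.44, 0.0528), Cxcl10 (-0.05, 0.935), Ptgs2 (-0.06, 0.881) and Nod1 (0.39, 0.0584) were not called. The means of Tnf (12.99 and 12.95 in wild type and cells labelled knockout), Cxcl10 (13.3 and 13.25) and Ptgs2 (12.58 and 12.52) lay near the highest value of any array, 13.67. Differences could be compressed there, which was not tested for these genes. Il10 was 1.22-fold higher (adjusted p = 0.0387), but the call was lost without any of the 6 infected arrays or the second uninfected wild-type array, with adjusted p up to 0.139 without the first infected array labelled knockout.

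Cell cycle genes were lower in 22 of 25 members in infected cells labelled knockout (22 adjusted over the list alone; median -0.76, adjusted p = 5.14e-42), and neutrophil markers higher in 6 of 15 (9 adjusted over the list alone; median 0.27, adjusted p = 1.20e-12). Sterol genes were higher in 8 of 17 (8 adjusted over the list alone; median 0.16, adjusted p = 2.21e-06), with Abcg1 1.47-fold higher, but in 3 of 17 without the first or the third infected wild-type array or without the third infected array labelled knockout. Those 3 calls held with an estimated correlation, and the following 10 did not. Fibroblast markers were higher at adjusted p = 3.10e-08 (adjusted p = 0.137 with an estimated correlation) in 6 of 12 members (8 adjusted over the list alone), or 2 without the third infected wild-type array, with Bgn 2.54-fold higher and Sparc at 9.28 on the array that stood apart against 7.75 and 7.64. Antigen presentation genes were higher in 5 of 17 (median 0.12) at adjusted p = 2.34e-05 (adjusted p = 0.0685 with an estimated correlation), and monocyte markers in 3 of 7 (median 0.38) at adjusted p = 0.00445 (adjusted p = 0.0530 with an estimated correlation). Adjusted p with an estimated correlation was 0.0634 for cytokines (median 0.17), 0.0530 for immediate early factors (0.12), 0.112 for osteoclast markers (0.21), 0.0881 for autophagy genes (0.09), 0.137 for macrophage identity genes (0.07), 0.105 for glycolysis genes (-0.10) and 0.112 for inflammasome genes (-0.04). The preset correlation gave adjusted p = 1.26e-05, 0.000361, 0.0261, 0.0385, 0.0408, 0.0408 and 0.0408 for these lists in that order. Interferon response genes were called higher in 1 of 25 members (2 adjusted over the list alone) with a median of 0.01 (adjusted p = 0.561), and antimicrobial effectors had a median of 0.009 and a mean of -0.02 (adjusted p = 0.588). In all, 1367 of 23410 probe sets were called, 677 higher and 690 lower, 152 of them at least 2-fold, and 2051 without the third uninfected array labelled knockout. The share higher was 49.5%, and 50.7% and 54.0% after the same 2 scalings.

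Genotype differences before and after infection overlapped. Of 1475 and 1155 genes called in uninfected and infected cells, 695 were called in both and 690 of these in the same direction, 287 higher and 403 lower, where independent sets would share 22.3 and 20.4. Averaged over infection states, 2723 probe sets differed by genotype, 1518 higher and 1205 lower, 169 of them at least 2-fold; averaged over genotypes, 12047 changed on infection, 4956 higher and 7091 lower, 1918 at least 2-fold. Genes lying beside a targeted gene can come from the strain of the stem cells in which it was targeted, so the 20 measured genes on each side of Nod2 were examined. In uninfected cells 5 of 40 were called against 7.39% of other genes (Fisher's exact test, two-sided p = 0.217), in infected cells 4 of 40 against 5.78% (exact p = 0.291) and averaged over both states 6 of 40 against 11.7% (exact p = 0.462, odds ratio 1.33, 95% interval 0.457 to 3.22). With 50 genes on each side the infected and averaged contrasts gave exact p = 0.00758 and 0.0177 and the uninfected contrast, with 10 of 100 called, exact p = 0.334. Benjamini-Hochberg adjustment ran over 18 such tests, which also covered 10 genes on each side and calls at an unadjusted p under 0.05. Adjusted, the last values were 0.0455, 0.0795 and 0.546. With 50 genes on each side and unadjusted calls, 31 of 100 were called in infected cells against 17.2% of other genes (exact p = 0.000756, adjusted 0.0136). Averaged over both states 36 of 100 were called (0.00664, adjusted 0.0455), and in uninfected cells 20 of 100 (0.899, adjusted 0.952).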

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

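The tests of a signal ceiling, of a single aberrant array for either part of its pattern, of the number of experiments, of macrophage content and of DNA from another strain, and the refits of 9 further interactions, were chosen only after the results were seen; the splits of the arrays and the count of genes called higher around Nod2 were chosen before theirs.

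The response to infection differed between the genotypes, by a test of the difference itself, for 156 probe sets. The median difference of the log2 changes, cells labelled Nod2 knockout minus wild type, was -0.60 for the interferon response list, -0.17 each for the inflammasome and the antimicrobial lists, -0.18 for antigen presentation, -0.11 for the NF-kB pathway and 0.13 for the cell cycle. The list calls for antigen presentation, the NF-kB pathway and the cell cycle were lost with an estimated correlation, as given above. Named genes with a difference below 0 were Saa3 (-2.07), Lcn2 (-1.80), Ms4a4c (-1.79), Ifi205 (-1.66), Ccl17 (-1.51), Ifi206 (-1.37), Mmp13 (-1.31), Cfb (-1.20), Ccl5 (-1.18), Ifit3 (-1.15), Ccl22 (-1.08), Csf1 (-0.91), Mx1 (-0.90), Ifit2 (-0.84), Nos2 (-0.84), Cd274 (-0.83), Zbp1 (-0.76), Mmp12 (-0.68), Ifit1 (-0.66), Mx2 (-0.61), Cybb (-0.54), H1f5 (-0.51) and Irf7 (-0.47). They rose less in cells labelled knockout, except that H1f5 fell in both genotypes and Irf7 read 10.83 there before and after infection. For Ccl5, Mmp13 and Cybb, with infected wild-type means of 12.87, 12.27 and 12.2, a signal ceiling was not tested and stays open. Differences above 0 were found for Cxcr4 (0.57), Kif20a (0.70), Ccl24 (0.85), Esco2 (0.86), Lif (0.87), Il23a (0.87), Tnfsf9 (0.89), Ccne1 (0.91), Ccnf (0.93), Cdca2 (0.94), Nsl1 (0.97), Mki67 (1.06), Depdc1b (1.09), Fbxo5 (1.10), Aspm (1.21), E2f8 (1.41) and Zfp961 (1.67). At least 1 of the infected means of Aspm (4.40 and 3.90 in wild type and cells labelled knockout), Depdc1b (4.43 and 4.29), Fbxo5 (4.68 and 4.49), Nsl1 (4.80 and 4.69), Esco2 (4.06 and 3.22), Cdca2 (5.34 and 4.65) and Ccnf (5.54 and 4.79) lay near or below the array medians. So did the uninfected wild-type means of Mx2 (3.53), Ccl22 (3.83), Lcn2 (4.12), Nos2 (4.14), Il23a (4.15), Ifi205 (4.27), Tnfsf9 (4.40), Lif (4.44), Ccl24 (4.62) and Ccl17 (4.68), and the size of all these differences is not secure. Of 9 genes named through other comparisons, Zbp1, Mmp12, Kif20a and Esco2 kept the call with each array left out. Cxcr4 and Ifit1 lost it in 4 and 5 of 12 such fits (adjusted p up to 0.0626 for both, without the second infected wild-type array) and Mx2 in 9 (0.0893, without the second infected array labelled knockout). Irf7, with adjusted p = 0.0427 on all arrays, lost it in 10 (0.127, without the second uninfected wild-type array), and H1f5, with 0.0497, in all 12 (0.142, without the second infected array labelled knockout). Ccl22, Ccl24, Mx1, Nos2, Fbxo5 and Ccnf lost theirs without the second infected wild-type array, among others. Of 100 splits of the 12 arrays, 4 gave as many calls, the real one included, and the highest other gave 206. This margin is narrow: exchanging the genotype labels in 1 infection state, a split drawn 0 times, gives 2723 calls because it turns the interaction into the averaged genotype difference. Apart from that exchange, the other splits mix wells of both genotypes within a group. Mixing widens the spread and lowers the calls, so this count cannot decide on chance.

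The first pattern weighed was that interferon response genes were higher in uninfected arrays labelled knockout and rose less on infection. A signal ceiling in infected cells as the whole cause is argued against by the 7 members with a wild-type infected mean under log2 10. Their median interaction was -0.55, with 6 of 7 below 0. The standard error of their mean was 0.144 across genes, which share the same arrays and are not independent replicates. The 18 members at log2 10 or more had a median interaction of -0.64 and a lowest of -1.66, with 18 below 0. For these brighter members a contribution of a ceiling stays open. A single aberrant array is argued against for the higher start by the fewest members called higher with 1 array left out, 23 of 25, and for the smaller rise by the median interaction, which came no nearer to 0 than -0.56 with 1 array left out, although the members called ranged from 6 to 18. A difference between the sets of cultures other than genotype stays open, since the design names 1 experiment. The genotype itself also stays open and could not be separated from it.

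The second pattern was that cell cycle genes were lower in arrays labelled knockout in both infection states. Fewer macrophages among the cells is argued against as the whole cause by the macrophage identity list, whose median difference in uninfected cells was 0.11 against -1.20 for the cell cycle list. Medians of other cell types' lists were 0.25 for neutrophil, 0.26 for monocyte and 0.46 for fibroblast markers but -0.02 for dendritic and -0.06 for T and NK cell markers. Only 1 of 12 dendritic and 2 of 13 T and NK markers lay above the array median on all uninfected wild-type arrays. Values below it are compressed, so these 2 medians cannot show whether such cells became more frequent. More cells of the types whose lists rose stays open. A difference between the sets of cultures other than genotype, such as age or density of the cells, may be the source and stays open because there was 1 experiment. The genotype stays open as well.

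The third pattern was that 72 of the 401 genes within 200 measured genes of Nod2 were called in the averaged genotype contrast, as many as in 3.01% of 11845 such windows. For 50 and 100 genes on each side the share was 4.75% and 4.998%. Neighbouring windows share most of their genes, and those on the chromosome of Nod2 were counted too, so these are not shares of independent windows. The windows with most calls lay on the same chromosome but off Nod2 by -191, -139 and -152 places for the 3 sizes from small to large. DNA of the stem cell strain beside the targeted gene may contribute, but the nearest 20 genes on each side held no clear excess (odds ratio 1.33, 95% interval 0.457 to 3.22), so it stays open. Cell cycle genes lying in that part are another candidate explanation. Counting only genes called higher, 30 against a median window of 26, 26.5% of windows held as many, which met the prediction. Counting only genes called lower, 42 against a median window of 20, 2.86% of windows held as many. These counts cannot separate this explanation from DNA of the stem cell strain, for which no direction was predicted. A direct count, added after the count of higher genes was seen, found 1 of 25 cell cycle list members there, Mcm5, against an excess of 22 genes called lower. The 42 called lower include replication genes outside that list, such as Orc6 (-0.76), Gins3 and Asf1b (-1.06), named after their values were seen. The cell cycle explanation therefore stays open too. Ccl22 (-0.715) and Ccl17 (-0.554), named above, are also among the 42, so DNA of the stem cell strain stays open for their differences. It is not excluded for Zfp961 either, whose distance from Nod2 is not given here.

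For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05; the real split gave 9193, 9726, 1753 and 1367 calls for infection in wild type, infection in cells labelled knockout, genotype in uninfected and genotype in infected cells, and the highest other 0, 0, 1 and 0, so that 1 split of 10 gave as many in each. For the averaged contrasts 1 of 100 splits gave as many calls, the real one, with 12047 against a highest other of 156 for infection and 2723 against 206 for genotype. The 156 came from exchanging the infection labels in 1 genotype, which turns the averaged infection change into the interaction. Apart from exchanges of whole groups, the other splits mix wells of both infection states or both genotypes within a group. Mixing widens the spread and lowers the calls. Low counts in the other splits were therefore built in, and none of these shares can decide on chance.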

How the results depend on the processing

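Leaving out both arrays that stood apart, and the members of lists called with arrays left out or with the block, were chosen only after the data were seen; the other alternatives were planned.

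Of 6426 checks of 357 named pairs of gene and comparison, 6065 kept direction and side of the threshold, 361 lost the call and 0 reversed. All these pairs were called to begin with, so that 0 gained a call was built in. Uncalled pairs near the threshold, such as Ifnb1 and Nod1 between genotypes in infected cells (limma adjusted p = 0.0528 and 0.0584), were not checked. In at least 1 setting 58 pairs lost a call, 56 of them with 1 array left out.

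The interaction count of 156 was the least stable. It was 83 without variance moderation, 255 with a variance trend and robust prior, 272 with array weights, 274 with dim probe sets removed and 64 over all probe sets of the table; the last 2 change how many probe sets are tested, and for the others the cause was not tested. With the replicate number as a block it was 99, and 10 interferon response members were called lower in place of 17. Replicate numbers showed no pairing: 18 same-number pairs of arrays correlated at -0.112 to 0.0846 after group means were removed. Without both arrays that stood apart 10 interferon members were called, with fewer arrays. After renewed quantile normalization and median centring the share above 0 went from 46.8% to 51.2% and 55.7% for the interaction, and the share higher from 51.9% to 48.2% and 46.5% for genotype in uninfected cells, from 49.5% to 50.7% and 54.0% in infected cells, from 37.1% to 41.7% and 29.8% for infection in wild type, from 37.2% to 44.5% and 34.1% in cells labelled knockout, from 41.1% to 45.6% and 34.4% for infection averaged and from 55.7% to 53.0% and 54.7% for genotype averaged. Array weights raised genotype in infected cells to 2237; the cause was not tested. The requirement of a 2-fold change left 1912, 1964, 20, 205, 152, 1918 and 169 probe sets by construction, in the order infection in wild type, in cells labelled knockout, interaction, genotype in uninfected, in infected, infection averaged and genotype averaged.

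Lists called by fry, which does not compare a list with other genes, numbered 19 and 20 for infection in wild type and in cells labelled knockout. With an estimated correlation 3 lists were called for the interaction, 8 for genotype in uninfected and 3 for genotype in infected cells. The correlation of the infection responses was 0.978 with dim probe sets removed and 0.965 after renewed quantile normalization. For 50 genes on each side of Nod2 the exact p was 0.00758 in infected cells, 0.0177 averaged and 0.334 in uninfected cells; the wider window is the only change.

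With 1 array left out, counts ranged from 8020 to 10142 for infection in wild type, 8618 to 9621 in cells labelled knockout, 60 to 220 for the interaction, 1187 to 2046 for genotype in uninfected, 917 (without the second infected wild-type array) to 2051 in infected cells, 11203 to 12120 for infection averaged and 2140 to 3150 for genotype averaged. Interferon members ranged from 23 to 24 higher in uninfected cells and 6 to 18 lower in the interaction, cell cycle members from 23 to 24 lower in uninfected and 21 to 22 in infected cells, and the response correlation from 0.962 to 0.965. The Nod2 transcript differed by -0.10 to 0.07 in uninfected cells, crossing 0 at 0.015, 0.068 and 0.025 without the first uninfected wild-type array or the second or the third uninfected array labelled knockout, none of them called, and by -0.26 to -0.07 in infected cells. Signal near background limits small changes of weakly expressed genes.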

Other observations

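The 10 gene families examined here and the markers of the array that stood apart were chosen only after the data were seen. The families described below were picked from the 10 for their nearly uniform movement, and others were mixed. Of 38 kinesins, 4 were higher and 12 lower in uninfected cells labelled knockout. Of 17 Kruppel-like factors, 5 rose and 6 fell on infection in wild-type cells.

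Replication-dependent histone genes, 27 of them measured, fell on infection in 22 cases in wild-type cells and 23 in cells labelled Nod2 knockout, and 15 and 14 were lower in arrays labelled knockout in uninfected and infected cells with 1 higher in each. Their median log2 change in wild-type cells was -0.90, and -0.76 and -0.95 after renewed quantile normalization and median centring. All 7 measured schlafen genes rose on infection in both genotypes (medians 2.72 and 2.02), and 5 were higher and 1 lower in uninfected cells labelled knockout. All 8 measured genes of the Ifi200 family rose in both (medians 3.18 and 2.27), and 6 had a called interaction below 0; whether a probe set reads more than 1 of these related genes was not tested.

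On the third infected array labelled knockout Col1a1 read 8.96 against 7.60 and 7.56 on the others of its group, Col3a1 7.04 against 5.53 and 5.59, and Bgn 8.15 against 7.06 and 7.09. Col1a1 lay between 7.34 and 7.70 on the uninfected arrays labelled knockout and between 6.90 and 7.01 on wild-type arrays. The source of this signal was not tested.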
